A study of Mus musculus with 4 samples.

How the data were processed

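Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in CD4+CD8+ double-positive (DP) thymocytes sorted from mouse thymus. The 4 samples formed 2 groups of 2 replicates, wild type (WT, mice with loxP sites in Chaf1b and no Cre) and knockout (KO, the same alleles with Cd4-cre). Per the labels, each deposited peak list was made from both replicates of its group, so the files held 1 list per group and no value per replicate.

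FastQC, Trim Galore, Bowtie2, GATK, Picard, deepTools 3.4.1 and MACS2 2.1.4 were named, per the submitters' processing notes, with the build mm10. The order and settings of these steps, including any shift of reads for the transposase cut, any removal of duplicates and any exclusion list, were not given in the sources used here. For each region the authors deposited a score, a fold enrichment at the summit, and the -log10 of p and of q. In the deposited lists the score was the whole part of the -log10 q times 10, and the lowest -log10 q lay just above that of a q of 0.05. The authors' fold enrichment was used only to describe, rank, match or filter regions. The summit lists repeated positions and -log10 q of the deposited peak lists and added nothing.

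Relative depth was worked out from the lists. MACS2 writes fold enrichment as (pileup + 1) / (background + 1) and p as a Poisson tail, so both unknowns can be solved at each summit. The solved pileups were whole within 0.05 on 100% of lines of both lists, with a largest deviation of 0.00208 in WT and 0.00173 in KO. Local backgrounds above the genome background came in steps of 0.02 on 100% of such lines. That step is what an extension of 200 bp and a window of 10 kb give, so that a local background divided by 0.02 gives the reads in 10 kb around the summit. The most frequent background, shared by 2636 WT and 736 KO summits, was taken as the genome background and so as the relative depth. Sequencing totals per library were not used here.

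Regions were compared by overlap of at least 1 bp. Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the assembly behind mm10. It gave the start and end of each gene but neither strand nor exons, and no genome sequence was used here. The planned promoter window was therefore replaced by a window of 1000 bp on either side of both annotated ends of a gene, called the gene end below. It holds the promoter and also the 3' end. Regions were classed as gene end, gene body or intergenic, and exons could not be set apart from introns. The planned motif counts were not run. Gene lists and the rule for named genes were fixed before the data were examined. The rule took Chaf1b, the 10 protein-coding genes with the highest WT fold enrichment at a gene end and no KO region there, and the 10 such genes with the KO and WT roles exchanged. It also took the 5 strongest regions of each list away from gene ends with no counterpart, and the 5 largest percentile differences in each direction among regions in both lists. Further, it took list members called in 1 list only or with the highest WT fold enrichment, and the Trav11 and Traj18 segments. Some list members that the rule takes are not reported here. Predicted genes were skipped, 2 while filling the WT set and 1 while filling the KO set.

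Each gene list was set beside 10000 random lists with as many genes in each of 20 bins of WT fold enrichment, drawn from the 7570 protein-coding genes with a WT region at a gene end. The percentile describes these lists and is no p-value. No test between groups was made, since each group had 1 list. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and not the spread between mice. No replicate check of any difference was possible. A region absent from a list was not called there, which does not say that the site was closed.

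The solver, the overlap and the matched percentile were tested on simulated data. All 2000 simulated pileups were recovered, and the 7627 regions kept in a simulated copy of the WT list were found with 0 false matches. Of 300 simulated sets of 40 regions with 50% of kept members removed, 95.7% fell below percentile 2.5, against 0.667% of sets with nothing removed. The planned gene lists had at most 18 members with a WT region. The simulation therefore does not say how often a loss in lists that short would show. The settings varied were the -log10 q threshold, the overlap rule, the gene end window, the matching column, the ranking column and the chromosomes. Leaving out regions with a local background over 4 times the genome background, matching on pileup and the random region sets for antigen receptor loci were added after the data were seen. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.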

Results

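Accessible regions of DP thymocytes were listed for WT mice and for mice in which Cd4-cre deletes Chaf1b, the p60 subunit of chromatin assembly factor 1 (CAF-1), which deposits histones H3 and H4 behind replication forks. DP thymocytes are the stage at which invariant natural killer T (iNKT) cells arise, and the series asks what Chaf1b does in early iNKT development. Each group had 2 replicates pooled into 1 list. The genome background was 1.37 reads in WT and 1.03 in KO, so the KO list rested on 0.752 times the depth of the WT list.

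The KO list was the shorter, with 7645 against 15215 in WT, a ratio of 0.502, and covered 2.46 Mb against 5.46 Mb. Median widths were 279 bp in KO and 307 bp in WT. Nearly all KO regions were also WT regions. Of the KO regions, 7080 overlapped a WT region (92.6%, 95% interval 92.0 to 93.2), and 565 did not. Of the WT regions, 7026 overlapped a KO region (46.2%, 45.4 to 47.0), and 8189 had none. The lists shared 2.17 Mb, with a Jaccard index of 0.376. At equal length, with the WT list limited to its 7645 regions of highest fold enrichment, 70.3% had a KO region.

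WT regions without a KO region were mostly weak. In the lowest decile of WT regions by fold enrichment, with a median of 4.22, 13.8% (12.1 to 15.6) had a KO region, and 8.34% of the lowest decile by q. In the highest decile, with a median of 12.1, the share was 97.0% (96.1 to 97.8). KO regions had a WT region in 77.6% (74.5 to 80.6) of the lowest decile and in 764 of 764 of the highest. Among the 2401 WT regions with a -log10 q of at least 20, 79 had no KO region.

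**Figure D1:**
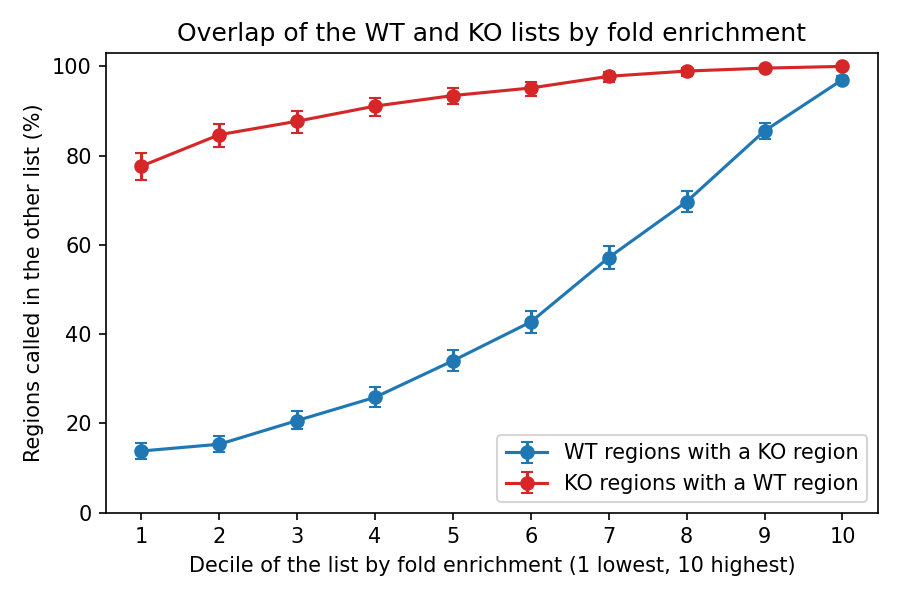
Share of regions of each list (y axis, percent) that overlap a region of the other list, by decile of the list ranked on fold enrichment (x axis). Points are shares with exact 95% binomial intervals as bars. WT regions (blue) go from 13.8% to 97.0%, and KO regions (red) from 77.6% to 100%.

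Regions at gene ends were kept more often than regions elsewhere. At gene ends, 4318 of 8040 WT regions had a KO region (53.7%, 52.6 to 54.8), against 1725 of 4653 in gene bodies (37.1%, 35.7 to 38.5) and 983 of 2522 between genes (39.0%, 37.1 to 40.9). Gene-end regions also had the higher median WT fold enrichment, 6.85 against 6.29 in gene bodies and 6.20 between genes. With the bins of WT fold enrichment weighted alike, the shares were 49.9%, 41.1% and 42.5%, so that gene ends stayed 7.42 percentage points above intergenic regions (bootstrap interval over regions 5.70 to 9.32). Matched on q the gap was 5.03 points. Matching on pileup was not run for these classes, so a difference in read number at equal fold enrichment was not set apart. Of protein-coding genes, 7570 had a WT region at a gene end and 4623 a KO region, with 4496 in both, 3074 in WT only and 127 in KO only. By chromosome the kept share went from 40.3% (37.1 to 43.5) on chromosome 4 to 52.0% (48.3 to 55.7) on chromosome 13 among the autosomes. On chromosome X it was 45.9% (40.5 to 51.3), from 342 WT and 164 KO regions, and on chromosome Y 14 of 25 WT regions were kept.

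Chaf1b itself (chromosome 16, 93883900 to 93906115) had a region at its low-coordinate end in both lists, at 93883721 to 93884062 in WT and 93883722 to 93883925 in KO. The position of the loxP sites was not given in the sources used here, so this region does not check the deletion. A WT region 2.17 kb beyond the other end of the gene, at 93908291 to 93908490, had no KO region. Among 13 genes of CAF-1 and other histone chaperones, 12 had a WT region at a gene end and 10 of these were kept in KO (83.3%, 51.6 to 97.9). The median of matched random lists was 8, and the list stood at percentile 92.7. Kept members with high WT fold enrichment were Ubn1 (12.7), a subunit of the HIRA complex, Pcna (11.3), the replication clamp that recruits CAF-1, and Asf1b (10.4), a histone H3-H4 chaperone. Hira (4.66), the chaperone of histone H3.3, and Atrx (5.48), a partner of Daxx in depositing H3.3, were called in WT only. Over gene bodies with 10 kb on each side, 17 of 25 WT regions were kept, against a random median of 13 (percentile 97.9).

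Genes that define DP thymocytes were mostly without a KO region at their ends. Of 27 members, 11 had a WT region there and 2 of these had a KO region (18.2%, 2.28 to 51.8), where matched random lists had a median of 5 (percentile 1.77). Of the 12 lists for which a percentile at gene ends could be given, some were too short to leave 2.5 to 97.5. With 0 of 3 kept the progenitor list stood at percentile 19.7, and with 3 of 3 kept the natural killer list at 72.9. The DP identity list was the only list outside these bounds with the planned window. The 9 members called in WT only were Rag1 and Rag2, which encode the V(D)J recombinase, Ptcra, Cd3d and Cd3g, which encode parts of the pre-T and T cell receptor complexes, Themis, a T cell receptor signalling protein, the nuclear factors Satb1 and Bcl11b, and the receptor Notch1. Their WT fold enrichments ran from 4.64 at Ptcra to 8.10 at Cd3g, with 6.57 at Rag1 (chromosome 2, 101649400 to 101649745), 7.19 at Rag2 (chromosome 2, 101624571 to 101624810) and 6.69 at Bcl11b (chromosome 12, 108004014 to 108004248). Called in both lists were Cd8b1 (WT 5.43), encoding the CD8 beta chain, and Tox (WT 9.21), a nuclear factor of T cell selection. With a window of 2000 bp, 4 of 15 members were kept, at percentile 4.87. Over gene bodies with 10 kb on each side the list was near its random median, with 21 of 65 WT regions kept against a random median of 22 (percentile 38.1).

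The list of V(D)J recombination and end joining, which shares Rag1 and Rag2 with the DP list, kept 7 of 10 members (percentile 53.4). Dclre1c (WT 13.7), which encodes the hairpin-opening nuclease Artemis, Hmgb2 (12.5), Atm (11.7), the kinase that responds to double-strand breaks, and Xrcc4 (10.3) were in both lists, and Xrcc5 (6.10), encoding Ku80, was in WT only. Of the genes of thymocyte survival and death, 1 of 4 was kept (percentile 26.1), and with a window of 2000 bp 5 of 7 (71.4%, percentile 91.9). Bcl2 (WT 8.0) was in both lists, while the pro-apoptotic genes Bcl2l11 (6.98) and Pmaip1 (3.79) and the deacetylase gene Hdac3 (4.27) were in WT only.

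Genes tied to early iNKT development stood close to their matched random lists, with 5 of 8 kept (62.5%, 24.5 to 91.5, percentile 67.3). Fyn (WT 11.5), a kinase downstream of SLAM receptors, Id2 (10.0), Ezh2 (9.31), the histone H3 lysine 27 methyltransferase, Egr1 (6.69), and Sh2d1a (4.64), the SLAM adaptor SAP, were in both lists. Hdac3, Bcl11b and Satb1 were in WT only. Id3, an inhibitor of E proteins, had a region in KO only (fold 4.93, chromosome 4, 136143692 to 136143900). Zbtb16, the iNKT transcription factor gene, had no region at a gene end in either list. Of 17 effector genes of iNKT and other T cells, 1 had a WT region, Fasl (5.90), and it had none in KO. The positive selection and maturation list kept 2 of 6 (33.3%, 4.33 to 77.7, percentile 17.0), with Ccr7 (WT 7.54) and Cd69 (6.52) in both lists and Klf2 (8.04), Runx3 (5.70) and Ccr9 (5.06) among those in WT only. Of the progenitor and double-negative stage genes, 0 of 3 were kept (percentile 19.7), with Kit (4.97), Cd24a (5.79) and Bcl11a (4.58) in WT only.

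DNA replication and cell cycle genes kept 10 of 17 (58.8%, 32.9 to 81.6, percentile 34.9), and housekeeping genes 9 of 18 (50.0%, 26.0 to 74.0, percentile 44.9). With a window of 2000 bp, 12 of 20 housekeeping genes were kept, at percentile 80.8. In both lists were Pcna, Ccna2 (WT 10.2), encoding cyclin A2, and Mcm4 (10.0) and Mcm3 (9.74) of the replicative helicase. In WT only were Top2a (7.94), Mcm6 (7.86), Cdt1 (6.45), Ccne1 (5.99), Mcm2 (5.58), Pola1 (5.48) and Cdk1 (5.38), and in KO only Cdc6 (5.90), a loader of the helicase. Housekeeping genes in WT only included Rab7 (7.59), Gapdh (7.32), Ppia (6.93), Tbp (6.43), Eef2 (6.33), Hprt (5.06), Eef1a1 (4.82) and Tubb5 (4.17). Among those in both lists, Vcp (10.1) and Pgk1 (10.1) had the highest WT fold enrichment.

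Markers of other lineages were nearly free of regions at gene ends. The germline, the neural, muscle, liver and pancreas, the myeloid, the erythroid and the stromal and epithelial lists had 0 members with such a region in either list. Of 8 B cell markers, Ebf1 (6.30) had a WT region and none in KO. Of 7 natural killer and innate lymphoid markers, Id2, Gzma (8.82) and Prf1 (7.91) were in both lists. Of the markers of these lists, 0 had a gene-end region in KO only.

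Over the T cell receptor alpha and delta segments (chromosome 14, 52427967 to 54224198) 43 WT and 11 KO regions were called, and each KO region overlapped a WT region. The kept share was 25.6% (13.5 to 41.2), 11 of 43, where random sets of WT regions matched on fold enrichment, added after the data were seen, had a median of 17 (percentile 1.08). Matched on pileup, the percentile was 15.4, and with a -log10 q of at least 10 it was 11.9, at a kept share of 57.1%. Nearly all of these regions lay by the variable segments, with 40 WT and 11 KO regions within 1 kb of a Trav segment, which put a region by 38 of 130 Trav segments in WT and by 9 in KO. Of the Trd segments 1 of 11 had a region nearby in WT and 0 in KO, and the 60 Traj segments and the Trac gene had 0 in either list. The invariant receptor of mouse iNKT cells joins Trav11 to Traj18. The region nearest Trav11 (53519303 to 53519859) was 3.67 kb away in WT and 39.6 kb away in KO. Next to the related Trav11n (53135122 to 53135678) a WT region lay 84 bp away and the nearest KO region 38.5 kb away, and for Trav11d the distances were 2.35 kb and 38.2 kb. These WT regions had folds of 5.46 at Trav11n, 4.58 at Trav11d and 6.69 at Trav11, with 12, 12 and 18 reads. Over all WT regions, the fold deciles that hold these values were kept at 20.6%, 13.8% and 42.7%, so a missing KO region is common at such folds. The interval and percentiles of the locus count each region as separate. WT regions recurred in pairs with nearly the same spacing, starting at 52863128 and 52863893, 53174070 and 53174862, and 53559447 and 53560251. The KO regions nearest Trav11d, Trav11n and Trav11 lay at these pairs. Regions by related segments may therefore not be independent, and whether their reads mapped uniquely was not tested. Traj18 (54200777 to 54200842) had its nearest region 26.4 kb away in WT and 53.0 kb away in KO. In the immunoglobulin heavy chain locus (chromosome 12), 29 of 59 WT regions were kept (49.2%, 35.9 to 62.5, percentile 23.5). The T cell receptor beta locus had 4 WT and 1 KO regions, the gamma locus 1 and 0, and the immunoglobulin kappa locus 2 and 3.

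**Figure D2:**
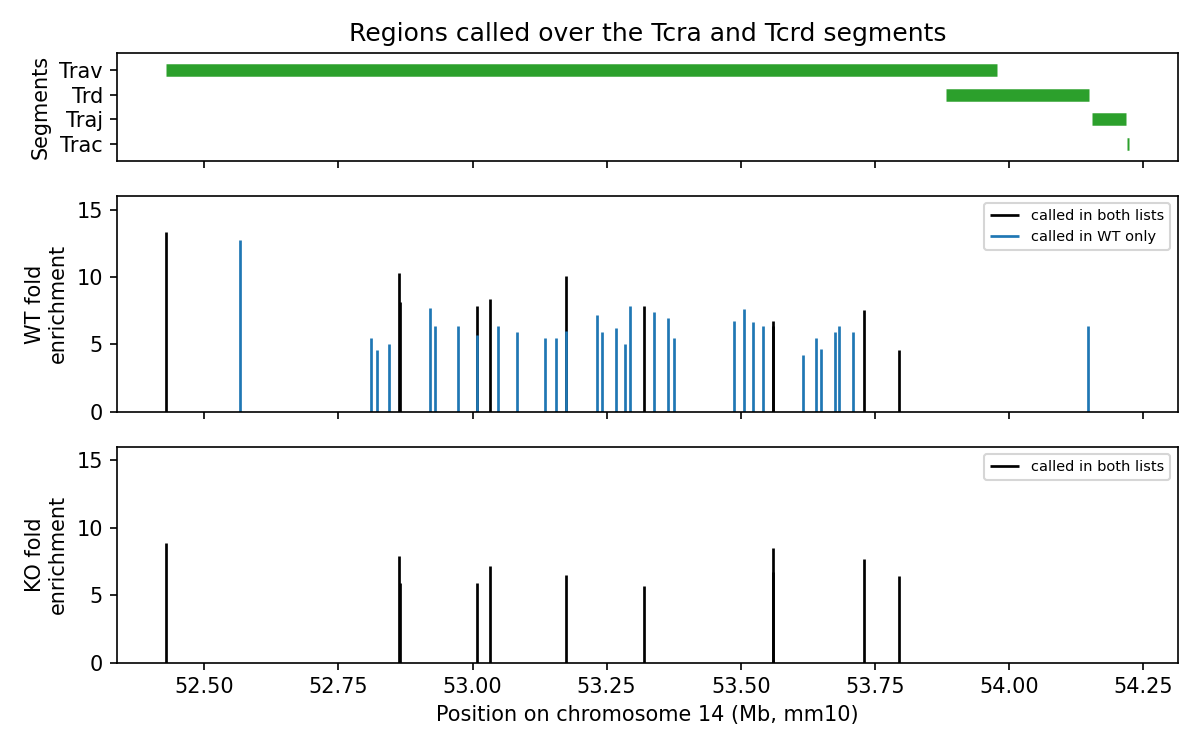
Regions called over the T cell receptor alpha and delta segments on chromosome 14 (x axis, Mb, mm10), with the span of the annotated segments on top and each region as a line whose height is the fold enrichment in its own list (y axis). Black lines are regions called in both lists and blue lines the WT regions without a KO region. The 11 KO regions and most of the 43 WT regions spread over the Trav part.

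Among protein-coding genes other than predicted ones, the highest fold enrichments at gene ends called in WT only were at Hmgn3 (fold 12.3, chromosome 9, 83146444 to 83146802), which encodes a nucleosome-binding protein, Zfp874a (11.9), Cfap300 (11.8), Borcs6 (11.7), Csrnp2 (11.6), the neighbours Orc3 and Rars2 (11.6), which share a region, Vbp1 (11.4), Ddb2 (11.3), a DNA damage recognition factor, and Mctp2 (11.1). Orc3 encodes a subunit of the origin recognition complex. Summit pileups of these regions lay between 26 reads at Vbp1 and 34 at Hmgn3.

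In the same set of genes, gene-end regions called in KO only reached lower values. The highest were at Nudt9 (fold 9.38, chromosome 5, 104046463 to 104046925, 20 reads), Wnt10a (8.02, 16 reads), Smim14 and Ube2k (7.38), which share a region, Rbmx (7.35), the olfactory receptor gene Olfr1351 (6.89), Gfod2 (6.80), Rpl36al and Mgat2 (6.72), which share a region, and Fbf1 (6.64). Over all regions without a counterpart, the median fold enrichment was 5.67 in WT and 5.41 in KO. With predicted genes counted, 127 protein-coding genes were called in KO only and 3074 in WT only. The highest values thus came from sets of unlike size and lists of unlike depth, and do not compare the strength of sites.

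Away from gene ends, the strongest WT regions without a KO region were 22.0 kb from Tjp1 (fold 13.0, chromosome 7, 65549826 to 65550175), inside Ankrd44 (12.02), inside Ext1 (12.01), inside Trp53bp1 (11.8), and 13.3 kb from Il12a (11.8, chromosome 3, 68676832 to 68677338). KO regions without a WT region were 168 kb from Nefm (9.17), 762 kb from Slitrk1 (8.86), 152 kb from Adcyap1 (8.57), inside Serpinb1c (8.49) and inside Mettl21a (8.26). Their summits held 17 to 19 reads. Exon and intron positions were not used here.

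The 6875 regions with a single counterpart in each list kept much of their order, with a Spearman correlation of fold enrichment of 0.664 across regions, which are not replicates. The largest percentile differences toward KO were at a region 28.9 kb from Cd200 (chromosome 16, 45352979 to 45353178), at percentile 10.2 in WT and 95.4 in KO, at the end of Ankrd42 (12.6 and 85.6), and inside Pdlim5 (10.2 and 82.1), Emc3 (7.38 and 78.0) and Pstpip1 (7.11 and 76.7). Summit pileups at the Cd200 region were 12 in WT and 27 in KO. Toward WT, the largest differences were at Adam9 and Tm2d2 (chromosome 8, 25016976 to 25017384), at percentile 91.1 in WT and 5.29 in KO, at Gtf2e1 and Rabl3 (87.6 and 6.27), at a region 104 kb from Zfat (93.8 and 13.4), at Swi5 and Golga2 (82.1 and 1.83) and at Morc2a (88.8 and 8.74). These extremes were picked from all 6875 regions and have no replicate check.

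The depth of the lists alone would put 42.9% of the reads of regions in both lists in KO. In the 1065 such regions with a summed summit pileup of 60 to 100 reads, KO held 38.6% (38.2 to 38.9). Below 25 reads, where a region enters both lists only with enough KO reads to be called, the share was 45.5% (44.5 to 46.4), and above 150 reads it was 48.0% (47.5 to 48.5). At 60 to 100 reads, the share was 37.8% (37.4 to 38.2) in 757 gene-end regions, 39.6% (38.8 to 40.3) in 213 gene-body regions and 42.4% (41.2 to 43.5) in 95 intergenic regions, an interval that holds the depth share. At 40 to 60 reads it was 37.5% (37.2 to 37.9) at gene ends and 39.2% (38.4 to 40.1) between genes. A region inside Cd4 stood far from the rest, with 18 reads in WT (Poisson interval 10.7 to 28.4) and 58 in KO (44.0 to 74.98).

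**Figure D3:**
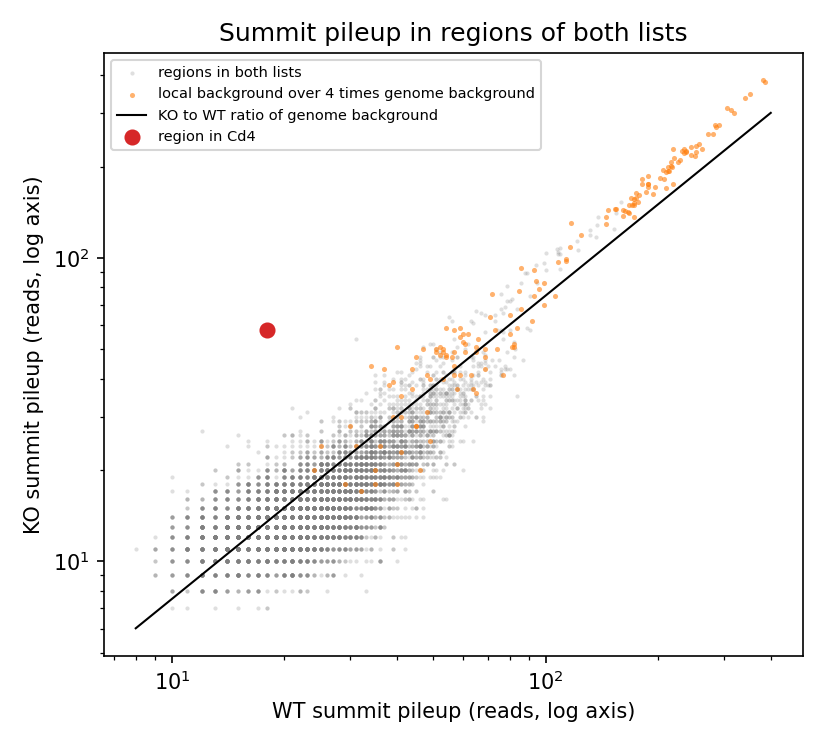
Summit pileup in WT (x axis, reads, log scale) and KO (y axis, reads, log scale) for the 6875 regions with a single counterpart in each list. The line is the depth ratio of 0.752, orange points are regions with a local background over 4 times the genome background, and the red point is the region in Cd4 with 18 reads in WT and 58 in KO.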

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

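The tests of the Cd4 region and of the shares of reads, the random region sets for the T cell receptor alpha locus, all matching on pileup and the bound of 2.5 were chosen after the results were seen, while the random gene lists and their other settings were planned.

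A region in the Cd4 gene (chromosome 6, 124885245 to 124885467) drew attention through a quantity outside the main comparison, the local background around each summit, which was 9.30 in KO and 1.86 in WT, a ratio of 5.00 where the depth ratio is 0.752 and the next highest of 6875 regions had 1.296. Opening of the called site alone is excluded, since the 395 reads gained over the depth-scaled WT number in 10 kb were 4.08 times the 96.9 reads that the called KO region can hold (lower bound 2.83). Extra copies of Cd4 sequence carried by the Cd4-cre transgene, present in KO mice only, are a candidate explanation that the lists do not decide: the only other region within 20 kb called in both lists (124900203 to 124900744, 11.96 kb beyond the gene) had a local background ratio of 0.901 (0.709 to 1.14), and how far such copies reach was not given in the sources used here. At its summit that region held 54 KO reads (Poisson interval 40.6 to 70.5) against 31 in WT (21.1 to 44.0). The KO list was nevertheless the shallower, and the fold enrichment there was 14.8 in KO and 7.96 in WT. A background over 10 kb may miss a gain confined to a short stretch, so the ratio of 0.901 does not speak against short extra copies. WT regions at 124879420 to 124879653 inside Cd4 (14 reads) and at 124903627 to 124903907 (17 reads) had no KO region. A broad opening of Cd4 without Chaf1b stays open too, as reads outside called regions were not used here.

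In the comparison of the lists, 8189 WT regions had no KO counterpart, against 565 KO regions without a WT counterpart. Lower depth as the whole cause, with depth taken from the genome background, is argued against by regions of both lists with 60 to 100 reads. KO held 38.6% (38.2 to 38.9) of their reads, against the 42.9% that depth gives. The share was 41.7% (40.9 to 42.5) at 100 to 150 reads, but 48.0% (47.5 to 48.5) above 150, which is over the depth share. Whether the genome background measures the depth that open sites received was not tested, so lower depth is not excluded. For intergenic regions lower depth stays open also because the ranges of reads disagree. Their interval held the depth share at 60 to 100 reads, at 42.4% (41.2 to 43.5), but lay below it at 40 to 60 reads, at 39.2% (38.4 to 40.1). A drop of the same size at all sites is argued against at 60 to 100 reads. There the KO share was 4.54 percentage points higher between genes than at gene ends (bootstrap interval 3.21 to 5.86). The shares were closer at 40 to 60 reads, 39.2% and 37.5% (37.2 to 37.9). Calls ran the opposite way, with a matched kept share of 49.9% at gene ends and 42.5% between genes. Only 95 intergenic regions entered at 60 to 100 reads. Whether some of them hold nearly equal reads for reasons other than accessibility was not tested, so a uniform drop is not excluded. Loss of Chaf1b and a KO library of lower quality cannot be told apart, because the files hold 1 list per genotype. A smaller share of reads in open sites may arise from either.

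Few DP identity genes and T cell receptor alpha regions were kept. For the DP identity genes, low WT fold enrichment cannot be told apart from a loss particular to these genes, since the list stood at percentile 1.77 of matched random lists with the planned window and at 4.87 with 2000 bp, while the other 5 settings put it lower than 2.5, at 1.98 with 500 bp, 1.82 where the region itself had to overlap, 1.03 matched on q, 0.60 matched on pileup and 0.24 with a WT -log10 q of at least 10, and regions over the gene bodies with 10 kb on each side stood at 38.1. For the T cell receptor alpha and delta locus the same holds, with percentile 1.08 over all its regions and 11.9 with a -log10 q of at least 10. These percentiles count each region as separate, although regions by related segments may not be independent. A low number of reads at the WT summits of the locus may be sufficient, since sets matched on pileup put it at percentile 15.4. A loss tied to Chaf1b stays open and untested, as no replicates could be compared.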

How the results depend on the processing

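No paired analysis was possible because each list pools both replicates of its group, and for the same reason no replicate could be left out. Of 140 alternative values, 112 stayed within the interval, the margin of 1.5 times or the side of the percentile bounds of the reported value. Matching on pileup, the percentiles of the T cell receptor alpha locus and leaving out regions of high local background were chosen after the data were seen, and the motif alternatives were not run. With a -log10 q of at least 10, 6921 WT and 2774 KO regions remained, and with at least 20, 2401 and 672. The share of WT regions with a KO region was 53.2%, 76.3% and 96.7% for a WT -log10 q of at least 5, 10 and 20, 72.6% and 70.3% for as many WT as KO regions by q and by fold enrichment, and 40.2% and 44.4% with KO summits within 100 and 250 bp. The share of KO regions with a WT region was 91.8% with an overlap of 50% of the shorter region, and 80% and 88.3% with summits within 100 and 250 bp. Ranked by q, the lowest and highest deciles of WT regions were kept at 8.34% and 98.8%, and the correlation of ranks was 0.686. The gap between gene ends and intergenic regions was 5.03 points matched on q and 5.68 points with summits within 250 bp. With a WT -log10 q of at least 10 the kept share was 81.8% for replication genes, 75% for housekeeping genes and 57.1% for the T cell receptor alpha locus, where 13 WT and 4 KO segments had a region nearby. Stricter thresholds remove weak regions by construction, which accounts for the fewer regions and higher shares. The cause of the moves under the summit rules, the overlap of 50% and the use of q was not tested. The DP identity list moved to percentile 4.87 with a 2000 bp window, and the T cell receptor alpha locus to 15.4 matched on pileup and 11.9 with a -log10 q of at least 10, and the cause of these moves was not tested. Of 68 values for the remaining gene lists, 1 left its interval or bounds, but intervals of short lists are wide: the survival list went from 25% kept (percentile 26.1) to 71.4% (percentile 91.9) with a 2000 bp window, the housekeeping list from percentile 44.9 to 80.8 with the same window, and, with a WT -log10 q of at least 10, the V(D)J list from percentile 53.4 to 10.1 and the early iNKT list from 67.3 to 40.9. At a genome background near 1 read, regions with summits of fewer than 7 reads were not called in either list, so weaker sites are out of reach.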

Other observations

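Gene families were chosen by symbol after the data were seen, and all 12 lay between percentiles 2.5 and 97.5 of their matched random lists. Among translation initiation factors, 28 of 36 genes with a WT region also had a KO region (77.8%, 60.8 to 89.9), against a median of 23 in matched random lists (percentile 97.495). Zinc finger genes kept 150 of 233 (percentile 46.6), ribosomal protein genes 29 of 56 (percentile 26.3), histone genes 19 of 41 (percentile 87.1), proteasome subunits 10 of 22 (percentile 16.4), and interleukins with their receptors 6 of 17 (percentile 18.2). Differences between families were not tested.

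Regions with a local background over 4 times the genome background numbered 216 in WT and 168 in KO. Whether they lie in repeated sequence was not tested. Of the WT ones, 161 had a KO region (74.5%). In the 163 such regions compared between both lists, local background was 0.874 times as high in KO as in WT at the median (quartiles 0.788 and 0.905). This was above the depth ratio of 0.752, and in the 41 regions with a WT local background above 60 the ratio was 0.885. The highest summit pileups were 386 in WT and 385 in KO, next to the 400 reads that a single read per position and strand with a 200 bp extension allows. In regions of both lists with a summed pileup above 150, KO held 48.0% of the reads. The share was alike in the 31 of these regions not over 4 times the genome background, 48.3% (47.1 to 49.5), and in the 87 over it, 48.0%.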
